A study of Homo sapiens with 8 samples.

How the data were processed

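Gene counts were taken from 2 tables the authors deposited, 1 for HEL and 1 for MOLM-13, with 4 libraries each. Per the labels, cells were grown in RPMI medium with fetal bovine serum, transduced with lentivirus expressing a control or a DDX6 shRNA and selected with puromycin; total RNA was extracted with the miRNeasy Micro kit and libraries were made with the NEBNext Ultra II RNA kit. Per the submitters' processing notes, STAR, SAMtools 1.12, DESeq2 and the GRCh38 genome were used; the role and order of these tools, the counter, the annotation release, the strand setting and the RNA selection step are not given in the sources used here. The deposited values are whole-number counts per gene, not normalized, with column totals that differ between libraries, and none of the replicates was pooled. Each column was assigned to its sample by the cell line, shRNA and replicate number in its name, and 0 columns were left unused. The HEL column names carry a hairpin number that the sample titles do not.

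Each table has 61544 entries in the same set of genes. Of these, 1348 share a symbol with another entry (0.023% of counts) and 20468 carry only an Ensembl identifier (0.645% of counts); 57123 matched GENCODE release 29 (GRCh38), which was used here for coordinates, lengths, GC content and overlaps between genes. Total counts in the replicate 1 and 2 libraries were 12093544 and 11342693 in HEL control, 11507674 and 10719829 in HEL DDX6 shRNA, 7888318 and 8174432 in MOLM-13 control, and 7979696 and 7985477 in MOLM-13 DDX6 shRNA. No pair of replicates was identical or within sampling noise: the chi-square per degree of freedom between replicates was 1.46 for HEL control, 1.61 for HEL DDX6 shRNA, 3.69 for MOLM-13 control and 1.77 for MOLM-13 DDX6 shRNA.

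The following choices were made before the data were examined. All 8 libraries entered 1 model with a mean for each of the 4 groups and no covariate, since a line alone leaves 2 residual degrees of freedom and the joint model leaves 4 (median prior degrees of freedom 40). Genes were filtered with filterByExpr (minimum count 10) over the 4 groups, which left 16499, libraries were scaled with TMM, and edgeR's quasi-likelihood test (glmQLFit, glmQLFTest) was run for DDX6 shRNA against control in each line and for the MOLM-13 change minus the HEL change. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The SE of a log2 fold change is its absolute value divided by the square root of the F statistic, and CPM values are TMM-scaled. Where a group had 0 counts, a fold is given as a bound against a floor of 3 counts over the group; with 1 to 3 counts, the ratio of counts is given with its exact 95% interval; with both groups at 3 counts or under, no fold is given. The bounds take the count of the other group as exact, so they are not lower confidence limits of the fold. The intervals cover counting error only. Calls shared by the lines were tested with Fisher's exact test, one-sided, over the 12316 genes that passed the filter within each line. The lines have separate control libraries, so no control is shared between the comparisons.

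Gene lists (24) were fixed beforehand: P-body and mRNA decay factors; myelomonocytic, erythroid, and megakaryocyte and platelet genes; self-renewal and progenitor regulators; cell cycle; p53 targets; apoptosis regulators; interferon-stimulated genes; inflammatory and NF-kB response; immediate early genes; ATF4 and unfolded protein response targets; JAK-STAT and MAPK feedback targets; myeloid tumour suppressors; cytosolic ribosomal proteins; nuclear oxidative phosphorylation genes; mitochondrially encoded mRNAs; cholesterol biosynthesis; glycolysis and hypoxia; heat shock; lymphoid markers; stromal, endothelial and epithelial markers; numbered ZNF genes; and replication-dependent histones. Some genes stand in more than 1 list. Each list was tested with camera at a preset correlation of 0.01 between genes, adjusted over the 24 lists within a comparison, and again with an estimated correlation. With the latter, the calls that held were megakaryocyte and platelet genes in HEL, interferon-stimulated genes in MOLM-13, and interferon-stimulated and cholesterol biosynthesis genes for the difference between lines. A call lost there is not by itself evidence of correlated members, since p also weakened for lists with an estimate below 0.01.

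Named genes were chosen by rule. In each line these were DDX6, and the 10 higher and 10 lower called genes with the largest fold change whose libraries did not overlap between groups and whose mean was at least 5 CPM in the higher group. From each called list up to 4 members with the smallest adjusted p in its direction were added, and from every other list up to 2 called members. For both lines the rule took the 10 higher and 10 lower shared calls ranked by the smaller of the fold changes, and for the difference the 5 most positive and 5 most negative, at a mean of at least 5 CPM. Genes without a symbol of their own, pseudogenes and sex-linked marker genes were left out of naming but not of counts. Results for some genes that the rule names are not reported here. Because strand-specific counting is not stated, genes were checked for exons shared with another gene on either strand (at least 100 bp, with the partner holding at least 10% of the gene's counts).

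Alternatives were RLE and upper-quartile scaling; no filter and a stricter filter (at least 1 CPM in at least 2 libraries); DESeq2's Wald test; each line fitted alone; the replicate number as a block; removal of a GC trend per library (spline with 5 degrees of freedom, centred, for the 98% of tested genes with a value), alone and with the block; a robust prior; a test against a fold of 1.2; adjusted p under 0.01 and under 0.1; fry; preranked camera; and leaving out each library. In the leave-one-out fits, which kept the set of genes tested, the lone sample of a group was assumed to vary like the others. Crossed replicate numbers and the GC trend without centring were added after seeing the data. The uncentred trend was the first form of that correction. It also rescales libraries, and it shifted the median gene by -0.0523 in HEL and -0.0403 in MOLM-13 on the log2 scale.

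The tests were checked on simulated counts drawn from the real means and library sizes. With the groups' own dispersions (0.000735 for HEL control, 0.000793 for HEL DDX6 shRNA, 0.00836 for MOLM-13 control, 0.00201 for MOLM-13 DDX6 shRNA) and no gene changed, edgeR gave an unadjusted p under 0.05 for 2.10% of 16271 genes in HEL and 8.11% in MOLM-13, and 0 calls after adjustment in either; DESeq2 gave 0.35% and 3.77%, and 0 calls. In this simulation the test therefore erred on the strict side in HEL and on the lenient side in MOLM-13. All simulated genes of a group shared 1 dispersion, so these rates need not hold for real genes that differ in spread. With 200 genes changed, it called 0 of 16064 unchanged genes in HEL and 44 of 16104 in MOLM-13, and of 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold it recovered 77.6%, 80.6% and 95.5% in HEL and 56.7%, 82.1% and 92.4% in MOLM-13. A planted list of 40 genes changed 1.3-fold in HEL was called (camera adjusted p = 6.23e-48) and 0 of the 24 real lists were. The simulated genes were drawn independently of each other, so this does not test camera on lists whose members are correlated. A planted GC trend in HEL gave 3833 calls among 16382 genes, and 0 with the trend removed. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.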

Results

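RNA sequencing measured transcript levels in HEL and MOLM-13 cells after lentiviral delivery of a control shRNA or an shRNA against DDX6, followed by puromycin selection. Both are established human acute myeloid leukaemia cell lines: HEL has erythroid and megakaryocytic features, and MOLM-13 is a monocytic line carrying a KMT2A fusion. Each of the 4 groups held 2 libraries, 8 in all. DDX6 is a DEAD-box RNA helicase needed to form P-bodies, the cytoplasmic granules that store untranslated mRNAs, and the series concerns RNA held in P-bodies in myeloid leukaemia. The comparison in each line therefore asked which transcripts changed level when DDX6 was reduced. Total counts per library were 10719829 to 12093544 in HEL and 7888318 to 8174432 in MOLM-13. At this depth, 3 counts in a library corresponded to 0.248 to 0.280 CPM (counts scaled to library size) in HEL and 0.367 to 0.380 CPM in MOLM-13. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

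DDX6 mRNA fell in both lines. The gene (ENSG00000110367, on the minus strand of GRCh38 chromosome 11, 118747766 to 118791149) had 2229 and 2150 counts in the HEL control libraries and 1124 and 1048 counts in the HEL DDX6 shRNA libraries. In MOLM-13 it had 978 and 966 counts in the control libraries and 516 and 558 counts in the DDX6 shRNA libraries. Mean levels went from 178 ± 2.24 to 95.8 ± 1.43 CPM in HEL and from 124 ± 2.99 to 71.0 ± 4.47 CPM in MOLM-13 (SD, n = 2). That left 53.8% and 57.4% of the control level. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, used for every gene named here, the log2 fold change was -0.90 ± 0.07 (SE) in HEL (adjusted p = 3.54e-14) and -0.80 ± 0.08 in MOLM-13 (adjusted p = 2.56e-11). The change in MOLM-13 minus that in HEL was 0.09 ± 0.11 on the log2 scale and did not pass the test (edgeR adjusted p = 0.636).

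**Figure D1:**
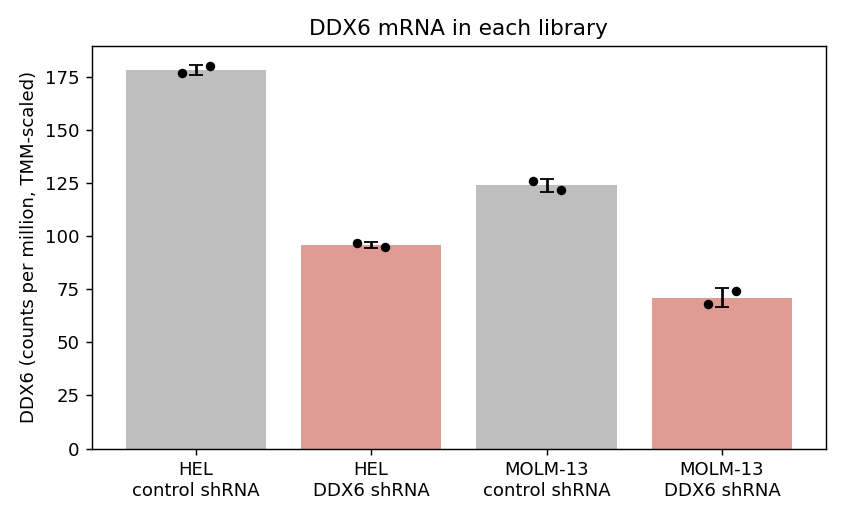
DDX6 mRNA in CPM (TMM-scaled, vertical axis from 0) for the 4 groups, with bars for group means, error bars for the SD and points for the 2 libraries of each group. The 4 DDX6 shRNA libraries lie between 67.9 and 96.8 CPM and the 4 control libraries between 122 and 180 CPM.

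The lines differed far more from each other than the treated cells did from their controls. Of the variance among the 8 libraries, 87% lay on a first principal component that parted HEL from MOLM-13, and 7.65% on a second component that parted DDX6 shRNA from control libraries in both lines. Among control libraries, 37 of 38 tested erythroid genes and 29 of 34 megakaryocyte and platelet genes were higher in HEL, and 38 of 42 tested myelomonocytic genes were higher in MOLM-13. The median log2 differences, HEL minus MOLM-13, were 7.402, 5.104 and -5.789. The expression filter ran over all 4 groups, so these lists can hold members with few counts in the line of lower level. A list not called in that line therefore says less.

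In HEL, genes of the megakaryocyte and platelet lineage rose together when DDX6 was reduced (24 of 34 tested members; adjusted p = 0.0279 with an estimated correlation). Among called genes with at least 5 CPM in the higher group and no overlap between the groups' libraries, the largest fitted rise was that of A2M (ENSG00000175899, chromosome 12, 9067664 to 9116229), which encodes the plasma protease inhibitor alpha-2-macroglobulin and went from 0.405 to 13.3 CPM (log2 fold change 4.99 ± 0.28, edgeR adjusted p = 3.33e-19). The platelet receptor gene CLEC1B rose by a log2 fold change of 4.01 ± 0.38, the neutrophil chemokine gene CXCL8 by 3.49 ± 0.26 and the proteoglycan gene VCAN by 3.22 ± 0.18 (edgeR adjusted p of at most 1.10e-11). DDIT4 (ENSG00000168209, chromosome 10, 72273920 to 72276036), a stress-induced inhibitor of mTOR signalling, had the largest fall among such genes, from 122 to 21.7 CPM (log2 fold change -2.49 ± 0.09, edgeR adjusted p = 5.46e-25). In all, 3417 of 16499 genes rose and 2322 fell in HEL, of which 768 rises and 198 falls were at least 2-fold. Rises made up 59.54% of the HEL calls. That share was 59.03% with RLE scaling, 53.18% with upper-quartile scaling and 52.04% with HEL fitted alone, so the size of the excess depended on these choices.

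Other large rises in HEL were those of LYVE1, a hyaluronan receptor of lymphatic vessels (log2 fold change 4.71 ± 0.34), the serine protease gene HTRA3 (4.01 ± 0.34), ACCSL (3.92 ± 0.36) and the keratin gene KRT79 (3.68 ± 0.18). The water channel gene AQP2 rose by 3.52 ± 0.20 and the semaphorin co-receptor gene NRP2 by 3.33 ± 0.21, and all 6 had edgeR adjusted p of at most 5.37e-12. After DDIT4, the next falls among such genes were those of the glutathione-degrading enzyme gene CHAC1 (-1.80 ± 0.14), BAIAP2L2 (-1.72 ± 0.25), the mitochondrial folate enzyme gene ALDH1L2 (-1.68 ± 0.18) and the stress transcription factor gene ATF3 (-1.65 ± 0.23). The pro-apoptotic gene BBC3 (-1.59 ± 0.14) and CHRM3-AS2 (-1.58 ± 0.13) came next, and all 6 had edgeR adjusted p of at most 2.63e-07. C9orf64 (-1.58 ± 0.16), ST8SIA1 (-1.57 ± 0.19) and MAMDC4 (-1.53 ± 0.22) fell as well (edgeR adjusted p of at most 3.61e-07).

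Megakaryocyte and platelet genes made up the HEL list with the clearest rise among the lineage lists: 24 of 34 tested members rose and 1 fell (27 and 2 when adjusted over the list alone; camera adjusted p = 8.81e-12). This call held when the correlation was estimated (adjusted p = 0.0279 with an estimated correlation). THBS1, which encodes thrombospondin 1, rose from 30.3 to 113 CPM (log2 fold change 1.90 ± 0.09), TREML1 by 1.52 ± 0.14 and the platelet collagen receptor gene GP6 by 0.96 ± 0.09 (edgeR adjusted p of at most 1.05e-11). The lists of lymphoid markers and of stromal, endothelial and epithelial markers also rose by camera at its preset correlation. Of 11 tested lymphoid markers, 7 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 0.00014, and adjusted p = 0.126 with an estimated correlation). Among them were the B-cell receptor genes CD79B (1.64 ± 0.14) and CD79A (1.25 ± 0.16), PRF1 (10.7 to 23.3 CPM) and CD2 (0.82 ± 0.14), at control levels of 5.44 to 10.7 CPM. Of 11 tested stromal, endothelial and epithelial markers, 6 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.00435, and adjusted p = 0.126 with an estimated correlation). Among them were COL1A1 (2.79 ± 0.47), PDGFRB (1.01 ± 0.19) and the endothelial receptor gene KDR (0.49 ± 0.08, from 68.9 to 96.9 CPM). The other lineage lists were not called in HEL. For myelomonocytic differentiation 12 of 42 tested members rose and 5 fell (12 and 6 adjusted over the list alone; camera adjusted p = 0.178). This list passed, as higher, with DESeq2 (0.0247) and in the fit of HEL alone (0.0491). The adaptor gene TYROBP rose from 22.0 to 54.1 CPM. Of 38 erythroid genes 12 rose and 4 fell (13 and 4 adjusted over the list alone; camera adjusted p = 0.232). Regulators of leukaemia self-renewal and progenitors had 10 rises and 8 falls among 39 (10 and 8 adjusted over the list alone; camera adjusted p = 0.875). The stem cell marker CD34 rose by 1.45 ± 0.11.

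Interferon-stimulated genes rose in HEL, 24 of 51 tested members against 1 that fell (25 and 1 adjusted over the list alone; camera adjusted p = 0.00378, and adjusted p = 0.127 with an estimated correlation). EPSTI1 rose by a log2 fold change of 1.27 ± 0.11, IFI6 by 1.04 ± 0.12 and IFI44 by 0.77 ± 0.08 (edgeR adjusted p of at most 1.60e-09). Of 18 tested heat shock genes 13 rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 5.60e-05, and adjusted p = 0.126 with an estimated correlation). The chaperone genes HSPB1, HSPH1 and HSP90AA1 rose by 0.79 ± 0.09, 0.55 ± 0.07 and 0.41 ± 0.05. Nuclear genes for oxidative phosphorylation rose, 32 of 68 tested members against 2 that fell (36 and 3 adjusted over the list alone; camera adjusted p = 5.19e-05, and adjusted p = 0.543 with an estimated correlation). NDUFB10 rose by 0.49 ± 0.08, NDUFS5 by 0.43 ± 0.07 and COX7B by 0.41 ± 0.07. Among the 13 mRNAs encoded in mitochondria 1, MT-CYB, rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.875). Replication-dependent histone genes rose in 7 of 17 tested cases and fell in 0 (8 and 0 adjusted over the list alone; camera adjusted p = 0.0175, and adjusted p = 0.158 with an estimated correlation). H2BC12 rose by 0.53 ± 0.10 and H2AC6 by 0.63 ± 0.12. Histone genes are near-identical copies that can share reads, and the call of this list was lost with DESeq2 (adjusted p = 0.12) and in the fit of HEL alone (adjusted p = 0.0874).

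Ribosomal protein mRNAs fell in HEL. Of the 79 cytosolic ribosomal protein genes 0 rose and 61 fell (0 and 67 adjusted over the list alone; camera adjusted p = 3.37e-20). The call was lost when the correlation between members was estimated (adjusted p = 0.356 with an estimated correlation). RPL13A fell from 1795 to 1207 CPM (log2 fold change -0.57 ± 0.05), RPS3 by 0.50 ± 0.06 and RPLP1 by 0.45 ± 0.06 on the log2 scale. Targets of ATF4 and the unfolded protein response fell on balance, with 19 of 39 tested members lower and 11 higher (19 and 11 adjusted over the list alone; camera adjusted p = 0.00362, and adjusted p = 0.178 with an estimated correlation). The serine synthesis genes PHGDH (-1.52 ± 0.07) and PSAT1 (-1.42 ± 0.07) were among the lower, together with DDIT4 and CHAC1. Cholesterol biosynthesis genes fell, 14 of 24 against 3 that rose (14 and 3 adjusted over the list alone; camera adjusted p = 3.33e-05, and adjusted p = 0.0907 with an estimated correlation). Among them were HMGCS1 (-0.79 ± 0.07) and the transcription factor gene SREBF2 (-0.47 ± 0.06); MVK (-0.89 ± 0.13) shares exons with MMAB on the opposite strand. Cell cycle genes fell in 22 of 51 cases and rose in 3 (23 and 3 adjusted over the list alone; camera adjusted p = 2.60e-05, and adjusted p = 0.178 with an estimated correlation). Among them were the replication licensing gene CDT1 (-0.69 ± 0.07), E2F2 (-0.92 ± 0.11) and CENPF (-0.39 ± 0.07), and also TYMS (-1.19 ± 0.08), whose exons overlap those of ENOSF1 on the opposite strand.

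Of 446 tested numbered ZNF genes, most of which encode zinc finger proteins, 118 fell and 18 rose in HEL (115 and 18 adjusted over the list alone; camera adjusted p = 2.96e-07, and adjusted p = 0.126 with an estimated correlation). ZNF395 fell by a log2 fold change of 1.48 ± 0.10, ZNF121 by 0.84 ± 0.07 and ZNF768 by 0.66 ± 0.09, and ZNF687 (-0.73 ± 0.09) overlaps PI4KB on the opposite strand. Myeloid tumour suppressor genes fell in 15 of 51 cases and rose in 3 (15 and 3 adjusted over the list alone; camera adjusted p = 0.0188, and adjusted p = 0.543 with an estimated correlation). Among them were CDKN1B (-0.43 ± 0.08), the cohesin gene SMC1A (-0.31 ± 0.07) and LATS1 (-0.37 ± 0.08). This call was lost without HEL control replicate 2 (camera adjusted p = 0.069) and with the directional fry test (adjusted p = 0.171). P-body and mRNA decay factors, 8 higher and 17 lower of 53 (9 and 17 adjusted over the list alone), did not pass the threshold in HEL (camera adjusted p = 0.0521) but did, as lower, with upper-quartile scaling (0.0265), among other alternatives. Without MOLM-13 control replicate 1 or 2 it had 0.02 and 0.0199, and without MOLM-13 DDX6 shRNA replicate 1 or 2 it had 0.0315 each. The antiproliferative gene BTG2 rose by 1.28 ± 0.07 and the deadenylase gene PAN2, which shares exons with CNPY2 on the same strand, had a log2 fold change of -0.91 ± 0.09.

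Further lists in HEL were not called. For p53 targets 10 of 34 rose and 7 fell (11 and 7 adjusted over the list alone; camera adjusted p = 0.875). The cell cycle inhibitor gene CDKN1A rose from 5.0 to 39.1 CPM (log2 fold change 2.96 ± 0.13, edgeR adjusted p = 6.28e-23). Apoptosis regulators had 12 rises and 8 falls among 37 (12 and 9 adjusted over the list alone; camera adjusted p = 0.875). The pro-apoptotic gene BAK1 rose by 1.04 ± 0.10. Inflammatory and NF-kB response genes had 11 rises and 6 falls among 33 (12 and 6 adjusted over the list alone; camera adjusted p = 0.165). The cytokine gene IL1B rose by 1.09 ± 0.07. Immediate early genes had 7 and 4 among 28 (7 and 5 adjusted over the list alone; camera adjusted p = 0.875). EGR1 rose by 1.21 ± 0.09. Feedback targets of JAK-STAT and MAPK signalling had 10 and 9 among 27 (10 and 9 adjusted over the list alone; camera adjusted p = 0.875). The kinase gene PIM1 fell by 0.68 ± 0.06. Glycolysis and hypoxia genes had 7 rises and 10 falls among 29 (9 and 13 adjusted over the list alone; camera adjusted p = 0.0701, and 0.0347, as lower, with upper-quartile scaling). It also passed without HEL DDX6 shRNA replicate 1 (0.0255) and without MOLM-13 control replicate 1 or 2 (0.0337 and 0.0336). The mitophagy gene BNIP3 (-1.23 ± 0.08) and VEGFA (-0.67 ± 0.07) fell. Among these uncalled HEL lists the median and mean of the members' log2 fold changes had opposite signs for p53 targets and for mitochondrially encoded mRNAs. For JAK-STAT and MAPK targets both were above 0 while camera's direction was down. DESeq2 called fewer genes in HEL, 2178 higher and 1383 lower, and without HEL control replicate 2 edgeR called 2250 and 1463. There were 1489 lower genes without HEL control replicate 1 and 1522 without HEL DDX6 shRNA replicate 1, and with the GC trend removed without centring, tried after seeing the data, 49.34% of HEL calls were higher (3224 and 3310) against 59.54% as reported.

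In MOLM-13, interferon-stimulated genes rose when DDX6 was reduced (adjusted p = 0.0312 with an estimated correlation). Cell cycle genes fell by camera's preset correlation, a call lost with the estimated one (adjusted p = 0.0577 with an estimated correlation). FBLN2 (ENSG00000163520, chromosome 3, 13549131 to 13638422), which encodes the extracellular matrix protein fibulin 2, rose from 0.5755 to 39.2 CPM (log2 fold change 6.06 ± 0.23, edgeR adjusted p = 3.98e-25). The serine protease inhibitor gene WFDC1 rose from 0.317 to 13.9 CPM (5.40 ± 0.36, edgeR adjusted p = 9.99e-17). The immediate early gene ARC had 0 counts over the control libraries and 155 over the DDX6 shRNA libraries. That was 53.6-fold higher against a floor of 3 counts over the group. The interferon-stimulated gene IFI27 had 0 and 91 counts, 31.5-fold higher against the same floor. ADAM28 (ENSG00000042980, chromosome 8, 24294040 to 24359018), a membrane metalloprotease gene, fell from 21.0 to 2.85 CPM (-2.88 ± 0.21, edgeR adjusted p = 1.25e-15). The monocyte genes FPR1 (-2.78 ± 0.35), CD14 (-2.78 ± 0.29) and S100A8 (-2.78 ± 0.28) fell with it (edgeR adjusted p of at most 1.76e-08). In all, 2981 genes rose and 2358 fell in MOLM-13, of which 862 rises and 292 falls were at least 2-fold. With the GC trend removed without centring, which also rescales libraries and was tried after seeing the data, 46.14% of MOLM-13 calls were higher against 55.83% as reported.

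Among the other large rises in MOLM-13, ANGPTL2 went from 2 to 84 counts, a ratio of 43.6 with a 95% counting interval of 11.7 to 365.9. The water channel gene AQP1 went from 3 to 83 counts, a ratio of 28.7 with an interval of 9.49 to 142.1. These intervals cover counting error only, and the folds against a floor take the count of the other group as exact. LINC02169 (log2 fold change 4.81 ± 0.31), the filamin gene FLNC (4.58 ± 0.44), the microtubule-associated protein gene MAP1A (4.48 ± 0.45) and HLA-DOA (4.46 ± 0.37), which encodes an MHC class II chain, rose with edgeR adjusted p of at most 5.65e-11. Further large falls were those of FCN1, which encodes ficolin 1 of monocytes (-2.49 ± 0.34), RUBCNL (-2.15 ± 0.12) and MIR210HG, the host transcript of a hypoxia-induced microRNA (-2.09 ± 0.34). The kinase gene LRRK2 (-2.04 ± 0.35), PPP1R14C (-1.85 ± 0.28) and SLCO4C1 (-1.80 ± 0.23) fell by less, and all 6 had edgeR adjusted p of at most 1.05e-05.

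Interferon-stimulated genes rose in 36 of 51 tested cases in MOLM-13 and fell in 0 (39 and 0 adjusted over the list alone; camera adjusted p = 4.08e-15, and adjusted p = 0.0312 with an estimated correlation). The antiviral synthetase genes OAS3 and OAS2 rose by log2 fold changes of 3.04 ± 0.20 and 2.34 ± 0.14, IFI6 rose from 17.0 to 95.3 CPM (2.49 ± 0.12) and LY6E by 0.90 ± 0.07 (edgeR adjusted p of at most 6.49e-15). Cell cycle genes fell in 44 of 51 cases and rose in 0 (45 and 0 adjusted over the list alone; camera adjusted p = 3.04e-25, and adjusted p = 0.0577 with an estimated correlation). CDT1 fell by a log2 fold change of 1.05 ± 0.08 and the ubiquitin-conjugating enzyme gene UBE2C went from 107 to 53.6 CPM. TYMS (-1.60 ± 0.09) and the flap endonuclease gene FEN1 (-1.15 ± 0.08) also fell, and they overlap ENOSF1 and TMEM258 on the opposite strand. Of the 79 ribosomal protein genes 0 rose and 41 fell in MOLM-13 (0 and 45 adjusted over the list alone; camera adjusted p = 2.52e-10, and adjusted p = 0.661 with an estimated correlation). RPL18 (-0.37 ± 0.06), RPL13A (-0.37 ± 0.05) and RPLP0 (-0.33 ± 0.05) were among those that fell. The directional fry test, which does not set the list against other genes, did not call the list (adjusted p = 0.0546). Lymphoid markers rose in 6 of 11 tested cases and fell in 1 (6 and 1 adjusted over the list alone; camera adjusted p = 0.000791, and adjusted p = 0.236 with an estimated correlation). The T-cell receptor subunit gene CD3D (2.84 ± 0.15), CD79B (2.40 ± 0.19) and PRF1 (2.49 ± 0.33) rose, and so did CD4, which monocytic cells also express, from 734 to 1249 CPM (0.77 ± 0.06).

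The remaining lists were not called in MOLM-13. For myelomonocytic differentiation 14 of 42 rose and 8 fell (17 and 8 adjusted over the list alone; camera adjusted p = 0.216, and 0.00667, as higher, with DESeq2). The aminopeptidase gene ANPEP rose by 2.48 ± 0.09 and the granule protease gene CTSG by 1.55 ± 0.07. Megakaryocyte and platelet genes had 8 rises and 2 falls among 34 (8 and 1 adjusted over the list alone; camera adjusted p = 0.176, and 0.0149, as higher, in the fit of MOLM-13 alone). CD9 rose by 1.84 ± 0.12. Erythroid genes had 6 and 5 among 38 (5 and 4 adjusted over the list alone; camera adjusted p = 0.798). FECH, which encodes the last enzyme of haem synthesis, rose by 0.75 ± 0.10. Self-renewal and progenitor regulators had 7 rises and 8 falls among 39 (7 and 8 adjusted over the list alone; camera adjusted p = 0.561). The transcription factor gene GATA2 fell by 0.94 ± 0.12. Myeloid tumour suppressors had 7 and 19 among 51 (7 and 19 adjusted over the list alone; camera adjusted p = 0.086). P-body and mRNA decay factors had 6 and 17 among 53 (6 and 17 adjusted over the list alone; camera adjusted p = 0.086). The helicase gene MOV10 rose by 0.96 ± 0.10. Stromal, endothelial and epithelial markers had 4 rises and 1 fall among 11 (4 and 1 adjusted over the list alone; camera adjusted p = 0.286). PECAM1 rose by 1.02 ± 0.06. Numbered ZNF genes had 48 and 45 among 446 (38 and 34 adjusted over the list alone; camera adjusted p = 0.437). Replication-dependent histones had 3 and 1 among 17 (3 and 1 adjusted over the list alone; camera adjusted p = 0.543).

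Stress and metabolism lists were likewise not called in MOLM-13. Targets of ATF4 and the unfolded protein response had 10 rises and 16 falls among 39 (11 and 16 adjusted over the list alone; camera adjusted p = 0.291). The disulfide isomerase gene PDIA6 rose by 0.96 ± 0.06 and STC2 fell by 1.69 ± 0.11. For cholesterol biosynthesis 9 of 24 rose and 3 fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.272). MSMO1 rose by 0.79 ± 0.10. Of 18 heat shock genes 4 rose and 4 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.963). HSPB1 rose by 0.69 ± 0.08 and HSPA1B, which shares reads with its near-identical copy HSPA1A, fell by 0.89 ± 0.16. Oxidative phosphorylation genes had 15 rises and 3 falls among 68 (13 and 3 adjusted over the list alone; camera adjusted p = 0.216). Mitochondrially encoded mRNAs had 4 and 0 among 13 (4 and 0 adjusted over the list alone; camera adjusted p = 0.168). Glycolysis and hypoxia genes had 9 and 9 among 29 (9 and 10 adjusted over the list alone; camera adjusted p = 0.963). The hexokinase gene HK1 rose by 0.69 ± 0.07. For p53 targets 3 of 34 rose and 8 fell (3 and 8 adjusted over the list alone; camera adjusted p = 0.153). MDM2 fell by 0.66 ± 0.08. Of 37 apoptosis regulators 5 rose and 8 fell (6 and 8 adjusted over the list alone; camera adjusted p = 0.67). BAX fell by 0.47 ± 0.07. Inflammatory and NF-kB response genes had 5 rises and 11 falls among 33 (5 and 12 adjusted over the list alone; camera adjusted p = 0.11). CXCL8 fell by 1.79 ± 0.28. Immediate early genes had 4 and 10 among 28 (5 and 10 adjusted over the list alone; camera adjusted p = 0.176). IER2 fell by 0.89 ± 0.10. JAK-STAT and MAPK feedback targets had 7 and 8 among 27 (7 and 8 adjusted over the list alone; camera adjusted p = 0.798). PIM1 rose by 0.64 ± 0.06. The median and mean had opposite signs in MOLM-13 for immediate early genes, apoptosis regulators, numbered ZNF genes, glycolysis and hypoxia, and heat shock, and for erythroid genes the mean was below 0 while camera's direction was up. The MOLM-13 control libraries differed from each other more than the other pairs did (common dispersion 0.00836, against 0.000735 to 0.00201 in the other groups), while the test shared 1 spread between all groups. DESeq2 called 1405 lower genes, and without MOLM-13 DDX6 shRNA replicate 2 edgeR called 1454. Without MOLM-13 control replicate 2 camera called 9 lists in MOLM-13, with oxidative phosphorylation (adjusted p = 0.000265), myeloid tumour suppressors (0.00403), mitochondrially encoded mRNAs (0.011), P-body and mRNA decay factors (0.013) and myelomonocytic differentiation (0.0279) in addition. Inflammatory genes passed, as lower, without MOLM-13 control replicate 1 (0.0374), and mitochondrially encoded mRNAs, as higher, without MOLM-13 DDX6 shRNA replicate 1 (0.016). Myeloid tumour suppressors (0.0121) and P-body and mRNA decay factors (0.0277) passed, as lower, without MOLM-13 DDX6 shRNA replicate 2.

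**Figure D2:**
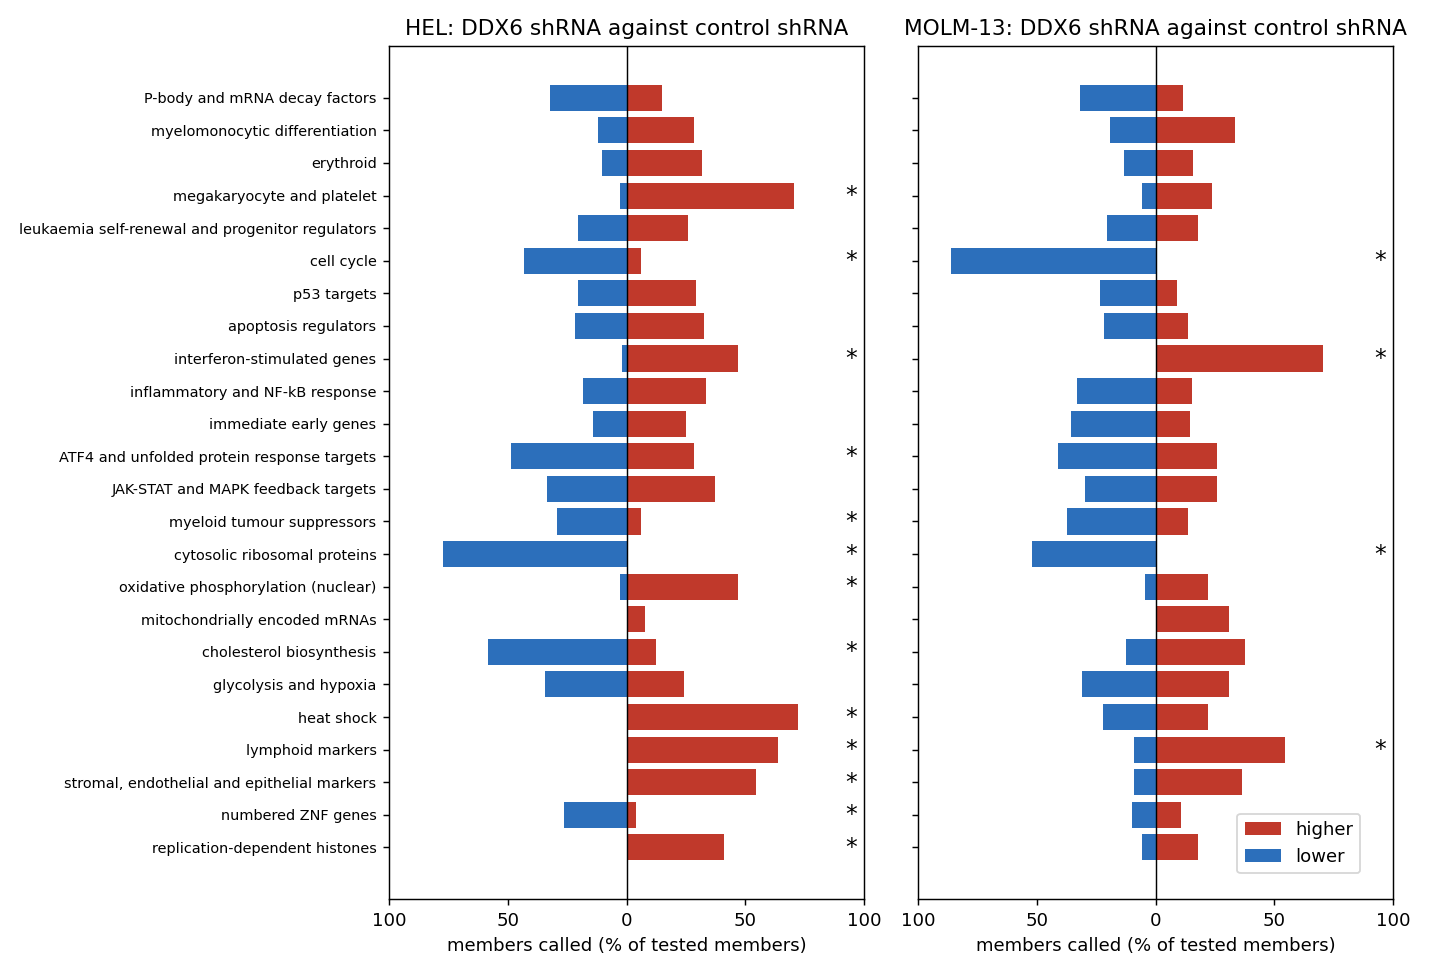
Share of the tested members of each gene list that were called higher (red, to the right) or lower (blue, to the left) with DDX6 shRNA, in percent, for HEL and MOLM-13; an asterisk marks lists with a camera adjusted p under 0.05 at the preset correlation of 0.01. In MOLM-13, 44 of 51 cell cycle genes lie to the left and 36 of 51 interferon-stimulated genes to the right, and in HEL 61 of 79 ribosomal protein genes lie to the left and 24 of 34 megakaryocyte and platelet genes to the right.

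Genes that changed in both lines moved mostly in the same direction. Of the 12316 genes that passed the expression filter within each line, 1267 rose in both, where lists drawn independently of each other would share 529.9 (odds ratio 6.49, Fisher's exact test, one-sided p = 5.60e-311). Likewise 885 fell in both, against 369.8 (odds ratio 5.07, Fisher's exact test, one-sided p = 1.63e-193). Opposite calls numbered 119 genes higher in HEL and lower in MOLM-13 and 134 genes lower in HEL and higher in MOLM-13, against 461.1 and 424.9 for independent lists. The log2 fold changes of the lines correlated across these genes with Pearson's r = 0.443 and Spearman's rho = 0.45; genes are not independent replicates, and the comparisons used separate control libraries. Ranked by the smaller of the changes, the genes of at least 5 CPM that rose most in both lines were HTRA3 (ENSG00000170801, chromosome 4, 8269765 to 8307111; log2 fold change 4.01 ± 0.34 in HEL and 4.37 ± 0.15 in MOLM-13), A2M (2.61 ± 0.20 in MOLM-13) and OTOF (2.36 ± 0.17 and 3.14 ± 0.11). The extracellular matrix gene ECM1 (2.34 ± 0.15 and 2.33 ± 0.09), DACT3 (2.11 ± 0.19 and 2.07 ± 0.24) and the angiotensin-converting enzyme gene ACE (2.01 ± 0.17 and 2.64 ± 0.29) came next. VCAN, MAP1A, the aquaglyceroporin gene AQP3 (1.77 ± 0.15 and 2.28 ± 0.11) and HLA-DRB5 (2.05 ± 0.25 and 1.71 ± 0.09), which can share reads with HLA-DRB1, followed. The genes of at least 5 CPM that fell most in both were MAMDC4 (-1.53 ± 0.22 and -1.65 ± 0.14), C9orf64 (-1.58 ± 0.16 and -1.52 ± 0.15) and ZNF395 (-1.48 ± 0.10 and -1.44 ± 0.12). C9orf64 is ENSG00000165118, on chromosome 9, 83938311 to 83956986. PLA2G6 (-1.28 ± 0.10 and -1.25 ± 0.20), HSD17B12 (-1.22 ± 0.11 and -1.48 ± 0.10), TYMS and the cannabinoid receptor gene CNR2 (-1.10 ± 0.18 and -1.37 ± 0.18) came next. C19orf54 (-1.07 ± 0.13 in each line), PTPN9 (-1.52 ± 0.10 and -1.04 ± 0.10) and the long non-coding RNA NORAD (-1.03 ± 0.06 and -1.06 ± 0.08), which binds Pumilio proteins, followed. All of these 20 genes passed edgeR's test with Benjamini-Hochberg adjustment in each line (adjusted p of at most 4.09e-06). With DESeq2, 1382 genes were called in the same direction in both lines, 509 of them lower, and with the GC trend removed without centring 1156 were higher and 1506 lower in both.

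**Figure D3:**
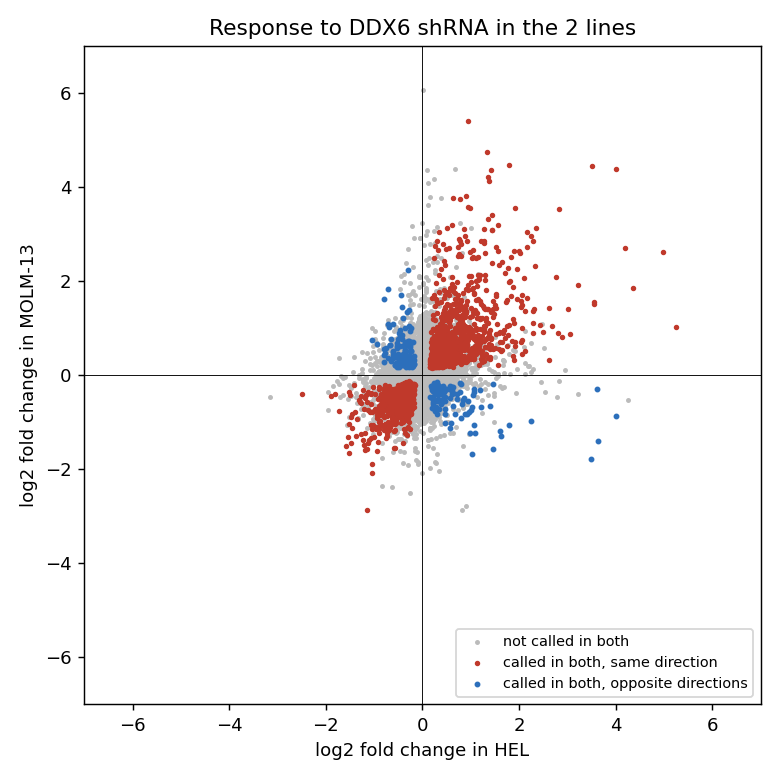
Log2 fold change with DDX6 shRNA in HEL (horizontal axis) and MOLM-13 (vertical axis) for the 12316 genes expressed in both lines, 1 point per gene. Genes called in both in the same direction are red (1267 higher and 885 lower), genes called in opposite directions blue (119 and 134), and the rest grey.

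The response itself differed between the lines for 2495 genes, by the test of the MOLM-13 change minus the HEL change: 1242 with a more positive change in MOLM-13 and 1253 with a more negative one. DESeq2 called 1494 such genes (803 more positive and 691 more negative), and edgeR called 1640 without HEL control replicate 1 (820 and 820), 1489 without HEL control replicate 2 (822 and 667) and 1634 without MOLM-13 DDX6 shRNA replicate 2 (670 more negative). There were 801 more negative genes without HEL DDX6 shRNA replicate 1 and 707 without MOLM-13 DDX6 shRNA replicate 1, and 1877 more positive ones without MOLM-13 control replicate 1. Interferon-stimulated genes rose more in MOLM-13, with 16 of 51 members more positive and 1 more negative (22 and 3 adjusted over the list alone; camera adjusted p = 8.98e-09, and adjusted p = 0.0408 with an estimated correlation). Among them were IFI44 (log2 difference 2.97, edgeR adjusted p = 5.82e-09) and OAS3 (2.70, edgeR adjusted p = 2.19e-12). Cell cycle genes were more negative in MOLM-13, 33 of 51 against 0 (36 and 0 adjusted over the list alone; camera adjusted p = 2.07e-18, and adjusted p = 0.0706 with an estimated correlation). Cholesterol biosynthesis genes were more positive, 13 of 24 against 1 (13 and 1 adjusted over the list alone; camera adjusted p = 1.40e-08, and adjusted p = 0.0408 with an estimated correlation), led by HMGCS1 (1.06, edgeR adjusted p = 1.18e-09). CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339) had a log2 difference of -2.85 (edgeR adjusted p = 1.47e-19): it rose in HEL, while its change in MOLM-13 was 0.12 ± 0.07 (edgeR adjusted p = 0.185). CXCL8 (ENSG00000169429, chromosome 4, 73740506 to 73743716) moved in opposite directions, with a log2 difference of -5.28 (edgeR adjusted p = 3.77e-14), and so did IL1B (-2.33, edgeR adjusted p = 1.49e-08) and PIM1 (1.32, edgeR adjusted p = 2.96e-16). The HEL column names carry a hairpin number and the MOLM-13 ones do not. A difference between the lines therefore cannot be told apart from a difference between hairpins.

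Heat shock genes were more negative in MOLM-13 than in HEL, 7 of 18 against 0 (10 and 0 adjusted over the list alone; camera adjusted p = 4.86e-06, and adjusted p = 0.117 with an estimated correlation). So were inflammatory and NF-kB response genes, 10 of 33 against 3 (14 and 4 adjusted over the list alone; camera adjusted p = 0.00378, and adjusted p = 0.304 with an estimated correlation). Oxidative phosphorylation genes followed, 11 of 68 against 0 (11 and 0 adjusted over the list alone; camera adjusted p = 0.00506, and adjusted p = 0.772 with an estimated correlation). So did p53 targets, 10 of 34 against 4 (10 and 4 adjusted over the list alone; camera adjusted p = 0.0274, and adjusted p = 0.215 with an estimated correlation). Immediate early genes were the last of these, 8 of 28 against 4 (10 and 4 adjusted over the list alone; camera adjusted p = 0.0395, and adjusted p = 0.234 with an estimated correlation). More positive in MOLM-13 were ribosomal protein genes, 7 of 79 against 0 (5 and 0 adjusted over the list alone; camera adjusted p = 0.00112, and adjusted p = 0.772 with an estimated correlation). Numbered ZNF genes were too, 42 of 446 against 3 (35 and 1 adjusted over the list alone; camera adjusted p = 0.00158, and adjusted p = 0.304 with an estimated correlation). Targets of ATF4 and the unfolded protein response were also more positive in MOLM-13, 15 of 39 against 6 (18 and 11 adjusted over the list alone; camera adjusted p = 0.0264, and adjusted p = 0.304 with an estimated correlation). Glycolysis and hypoxia genes followed, 9 of 29 against 4 (9 and 5 adjusted over the list alone; camera adjusted p = 0.0274, and adjusted p = 0.61 with an estimated correlation), with a mean difference below 0. The replicate number as a block ended the difference calls of p53 targets, immediate early genes, ATF4 targets and glycolysis and hypoxia (camera adjusted p = 0.0541 for each). Leaving out single libraries also ended some of the difference calls (camera adjusted p). Without HEL control replicate 2 it was 0.0642 for p53 targets, 0.0543 for immediate early genes and for glycolysis and hypoxia, and 0.0679 for oxidative phosphorylation. Without HEL DDX6 shRNA replicate 2 it was 0.0698 for p53 targets, 0.083 for immediate early genes and for ATF4 targets, and 0.175 for glycolysis and hypoxia. Without MOLM-13 control replicate 1 it was 0.123 for p53 targets and 0.0508 for immediate early genes. Without MOLM-13 control replicate 2 it was 0.0541 for inflammatory genes, 0.128 for immediate early genes and 0.694 for oxidative phosphorylation. Without MOLM-13 DDX6 shRNA replicate 1 it was 0.0655 for p53 targets and 0.0619 for immediate early genes. Without MOLM-13 DDX6 shRNA replicate 2 it was 0.0548 for immediate early genes, ATF4 targets and glycolysis and hypoxia, and 0.182 for oxidative phosphorylation. The directional fry test did not call ribosomal proteins (adjusted p = 0.331), oxidative phosphorylation (0.328), glycolysis and hypoxia (0.0772) or numbered ZNF genes (0.064). The other 12 lists were not called in this comparison, with camera adjusted p from 0.0536 for mitochondrially encoded mRNAs to 0.986 for P-body and mRNA decay factors. Mitochondrially encoded mRNAs passed, as more positive, with RLE (0.0382) and upper-quartile scaling (0.0266), among other alternatives. Among these, camera's direction was up while the median, the mean or both were below 0 for P-body and mRNA decay factors, erythroid genes, self-renewal regulators, JAK-STAT and MAPK targets and stromal markers.

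Among the 5 genes with the most positive and the 5 with the most negative fitted difference at a mean of at least 5 CPM, FBLN2 was at 172 CPM in HEL controls and at 174 CPM with DDX6 shRNA, unlike its rise in MOLM-13 (log2 difference 6.05, edgeR adjusted p = 1.39e-22). IFI27 had a difference past the test (edgeR adjusted p = 2.67e-06) with 0.616 CPM in HEL controls and 0.573 CPM with DDX6 shRNA. TMEM163 and ROBO4 had 0 counts over the MOLM-13 controls. Against a floor of 3 counts over the group they were 5.88-fold and 7.96-fold higher with DDX6 shRNA. In HEL they rose by 0.51 ± 0.09 and 1.58 ± 0.13 (edgeR adjusted p of the difference 0.00217 and 0.00995). RAB7B and the insulin receptor gene INSR had 0 counts over the HEL controls. Against that floor they were 8.31-fold and 3.61-fold higher with DDX6 shRNA (edgeR adjusted p of the difference 0.000945 and 0.00326). SLCO2B1 rose in HEL by 1.69 ± 0.09. In MOLM-13 0 counts of it remained of 5, 1.61-fold lower against that floor. CRB2 was 2.57-fold lower there against the floor, with 0 counts of 8 (edgeR adjusted p of the difference for SLCO2B1 and CRB2 0.00541 and 0.0222). GGT1, which shares sequence with other copies of its family, went from 6 to 0 counts in HEL, 1.85-fold lower against the floor. It rose from 3.96 to 11.2 CPM in MOLM-13 (edgeR adjusted p of the difference 0.00648). All folds against the floor take the count of the other group as exact, so they do not set a least size of the change. Several of these low-count calls rested on single libraries. The difference for CRB2 did not pass without MOLM-13 control replicate 2 (edgeR adjusted p = 0.369) or DDX6 shRNA replicate 1 or 2 (0.128 and 0.134). The ROBO4 difference was lost without MOLM-13 control replicate 1 or 2 (0.0502 and 0.0624) or DDX6 shRNA replicate 2 (0.0722), and the GGT1 difference without HEL control replicate 1 (0.0938). The falls themselves also did not pass for SLCO2B1 in MOLM-13 without control replicate 1 (0.103) or DDX6 shRNA replicate 1 or 2 (0.14 and 0.147). The same held for CRB2 in MOLM-13 without control replicate 2 (0.321) or DDX6 shRNA replicate 1 or 2 (0.102 and 0.107), and for GGT1 in HEL without control replicate 1 (0.151) or DDX6 shRNA replicate 1 or 2 (0.132 and 0.114).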

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

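Of the tests that weigh the patterns given first here, the scaling and hairpin tests of interferon-stimulated genes and the GC test of ribosomal protein genes were chosen only after the result was seen, and the criterion of the scaling test was changed 3 times after its values were known: from camera's call to the list's lower quartile, then to the interval of its median, then to both of these together. Interferon-stimulated genes rose in both lines, with list medians of 0.20 in HEL and 0.72 in MOLM-13 on the log2 scale (0.20 over 51 and 0.73 over 50 members when those with 0 counts in a group were set to their bound); the call was lost with an estimated correlation in HEL (adjusted p = 0.127) and held in MOLM-13 (adjusted p = 0.0312). With RLE scaling, upper-quartile scaling and each line fitted alone the median gene shifted by at most 0.0348 in HEL and 0.0127 in MOLM-13. In MOLM-13 the list's lower quartile of 0.3473 and the exact 95% interval of its median (0.4026 to 0.8817) lay above that shift, which argues against scaling as the whole cause. In HEL the interval (0.0559 to 0.3978, with genes taken as independent) lay above the shift. This argues against scaling as the whole cause of the rise in the list's median. The lower quartile of -0.001 did not lie above the shift, so part of the members showed no rise beyond scaling. By the last criterion, which asked for both, HEL stayed undecided, so the verdict there depends on the criterion. A biological rise with less DDX6 stays open as a hypothesis, and with 1 DDX6 shRNA group per line it cannot be told apart from a response to the hairpin.

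Ribosomal protein mRNAs fell in both lines, with list medians of -0.2468 in HEL and -0.1445 in MOLM-13, by calls that were lost with an estimated correlation (adjusted p = 0.356 and 0.661 with an estimated correlation). Genes matched on length and expression had medians of 0.1446 and 0.1392, and 100 of 100 draws lay above 0.5 times the list median. Their median lengths were 1021 and 1028 nt, against 1017 nt for the list. This argues against a loss of transcripts of that annotated length. Lengths were those of the longest principal annotated transcript, which can exceed the expressed one, and the match weighted length over expression. A loss of shorter transcripts therefore stays open. With the GC trend removed the medians were -0.2567 and -0.1476 and camera at its preset correlation called the list (adjusted p = 3.86e-24 and 4.09e-12), which argues against GC content as the whole cause. The summed level of 1295 ribosomal protein pseudogenes changed by -110.4 and -332.1 CPM while the list lost 8435.5 and 12534 CPM, which argues against reads moved to the copies. A lower level of these mRNAs with less DDX6 is a biological hypothesis that stays open, together with a response to the hairpin, since the labels give 1 DDX6 shRNA group per line.

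At least 2-fold changes were mostly rises. At a mean of at least 5 CPM there were 246 rises and 47 falls in HEL and 407 and 90 in MOLM-13, or 5.234 and 4.522 rises per fall, which argues against fold noise at low counts. The fitted median of genes under 1 CPM was 0.1129 over 1645 genes in HEL and 0.0505 over 1412 in MOLM-13, which argues against background reads, since these would lift such genes together. More rises than falls with less of a protein that represses mRNAs is a biological hypothesis. A response to the hairpin stays open here too, because each line had 1 DDX6 shRNA group.

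The labels do not say whether both lines received the same hairpin, so the differences below cannot be told apart from a hairpin difference. The other results given here drew attention because the change with DDX6 shRNA differed between the lines by the test of the difference itself. It did for 2495 genes; DESeq2 called 1494, and edgeR called 1640 without HEL control replicate 1, 1489 without HEL control replicate 2 and 1634 without MOLM-13 DDX6 shRNA replicate 2. By camera the lists concerned, with their adjusted p, were cell cycle genes (2.07e-18), interferon-stimulated genes (8.98e-09), cholesterol biosynthesis (1.4e-08), heat shock (4.86e-06), ribosomal proteins (0.00112), numbered ZNF genes (0.00158), inflammatory and NF-kB response (0.00378), oxidative phosphorylation (0.00506), ATF4 and unfolded protein response targets (0.0264), p53 targets (0.0274), glycolysis and hypoxia (0.0274) and immediate early genes (0.0395). The calls that held with an estimated correlation were those of interferon-stimulated and cholesterol biosynthesis genes (adjusted p = 0.0408 for each). Leaving out 1 library ended some of these calls. Without HEL control replicate 2, p53 targets had an adjusted p of 0.0642, immediate early genes and glycolysis and hypoxia 0.0543 and oxidative phosphorylation 0.0679. Without HEL DDX6 shRNA replicate 2, it was 0.0698 for p53 targets, 0.083 for immediate early genes and for ATF4 targets, and 0.175 for glycolysis and hypoxia. Without MOLM-13 control replicate 1, p53 targets had 0.123 and immediate early genes 0.0508, and without MOLM-13 control replicate 2 inflammatory genes had 0.0541, immediate early genes 0.128 and oxidative phosphorylation 0.694. Without MOLM-13 DDX6 shRNA replicate 1, p53 targets had 0.0655 and immediate early genes 0.0619. Leaving out MOLM-13 DDX6 shRNA replicate 2 gave 0.0548 for immediate early genes, ATF4 targets and glycolysis and hypoxia, and 0.182 for oxidative phosphorylation.

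Named genes whose log2 change (MOLM-13 minus HEL) was more positive in MOLM-13 by edgeR's test were, among the largest changes of either line, FBLN2 (6.05), WFDC1 (4.46), FLNC (3.61), MAP1A (2.68), DDIT4 (2.10), BAIAP2L2 (2.08), CHRM3-AS2 (1.74), ALDH1L2 (1.66), BBC3 (1.55), CHAC1 (1.40) and ATF3 (1.23). Among interferon-stimulated and inflammatory genes they were IFI44 (2.97), OAS3 (2.70), EPSTI1 (1.58), IFI6 (1.45), LY6E (0.51) and CD40 (0.94). In the ATF4, metabolic and mitochondrial lists they were PSAT1 (1.21), PHGDH (1.16), HMGCS1 (1.06), MSMO1 (0.95), INSIG1 (0.52), SREBF2 (0.43), BNIP3 (0.92), HK1 (0.66), MT-ND4L (0.46) and MT-CO1 (0.23). Lineage and marker genes with a more positive change were ANPEP (2.35), PRF1 (1.37), FECH (0.91), CD9 (0.78), CD79B (0.76), PECAM1 (0.72) and CD4 (0.44). The rest were PIM1 (1.32), SOCS1 (0.87), OTOF (0.78), ZNF768 (0.68), MOV10 (0.67), CDKN1B (0.66), PTPN9 (0.48), ZFP36L2 (0.47), PAN2 (0.41), ZNF121 (0.38) and RPS3 (0.29). More negative in MOLM-13 were, among the largest changes of either line, CXCL8 (-5.28), CLEC1B (-4.87), ADAM28 (-3.71), FPR1 (-3.68), RUBCNL (-3.21), LRRK2 (-2.39), A2M (-2.38), NRP2 (-2.20), PPP1R14C (-2.11), SLCO4C1 (-1.66) and VCAN (-1.31). Lineage and marker genes with a more negative change were COL1A1 (-3.26), COL3A1 (-2.62), CTSG (-2.01), GATA2 (-0.99), THBS1 (-0.80) and TYROBP (-0.70). In the p53, apoptosis, inflammatory and immediate early lists they were CDKN1A (-2.85), IL1B (-2.33), EGR1 (-1.90), IER2 (-0.93), BAK1 (-0.69), BAX (-0.59), MDM2 (-0.52) and TNFAIP8 (-0.40). Others were BTG2 (-0.98), FEN1 (-0.79), HSPA1B (-0.74), FKBP4 (-0.68), UBE2C (-0.59), NDUFB10 (-0.44), TYMS (-0.41), COX7B (-0.40), CDT1 (-0.36), NDUFS5 (-0.36), HSP90AA1 (-0.33) and MT-CYB (-0.32). Where a group had 3 counts or fewer, only the edgeR adjusted p of the difference is given: IFI27 2.67e-06, AQP1 0.000122, S100A8 0.0498, TMEM163 0.00217, GGT1 0.00648, ROBO4 0.00995, SLCO2B1 0.00541, CRB2 0.0222, INSR 0.00326 and RAB7B 0.000945. The size of some differences moved when 1 library was left out, in either direction. FLNC went from 3.61 to 1.98 without HEL control replicate 1, and CHRM3-AS2 from 1.74 to 0.59 without MOLM-13 DDX6 shRNA replicate 1. NRP2 went from -2.20 to -2.50 without MOLM-13 control replicate 2. Some of these differences did not pass edgeR's test when 1 library was left out. Without HEL control replicate 1, the adjusted p was NRP2 0.105, ATF3 0.0539, CHRM3-AS2 0.0765, FLNC 0.639, S100A8 0.18, RUBCNL 0.0534, CDT1 0.0775, RPS3 0.101, NDUFS5 0.0571, MT-CYB 0.0886, CD79B 0.0893, ZNF121 0.0683, TNFAIP8 0.0519, MT-CO1 0.0612, OTOF 0.0591, PTPN9 0.0737 and GGT1 0.0938. For the fit without HEL control replicate 2, it was CHRM3-AS2 0.0722, S100A8 0.0565, PAN2 0.239, THBS1 0.135, TYMS 0.103, CDT1 0.101, NDUFS5 0.0554, NDUFB10 0.0675, CD79B 0.107, ZNF121 0.1, CD9 0.117, TNFAIP8 0.103, SOCS1 0.0689, MT-CO1 0.222 and OTOF 0.171. Without HEL DDX6 shRNA replicate 1, the adjusted p was NRP2 0.0573, S100A8 0.333, PPP1R14C 0.182, PAN2 0.111, THBS1 0.0735, TYMS 0.137, CDT1 0.108, ZNF121 0.178, TNFAIP8 0.0643 and SOCS1 0.0517. For the fit without HEL DDX6 shRNA replicate 2, it was CHRM3-AS2 0.062, S100A8 0.0812, PAN2 0.0941, THBS1 0.0518, RPS3 0.0517, CD79B 0.0983, CD9 0.0529, TNFAIP8 0.0544, MT-CO1 0.124, COL3A1 0.156, OTOF 0.0696 and PTPN9 0.11. Leaving out MOLM-13 control replicate 1 gave NRP2 0.299, THBS1 0.242, TYMS 0.0569, CD79B 0.0653, TNFAIP8 0.107, CD40 0.109 and ROBO4 0.0502. With MOLM-13 control replicate 2 left out, values were NRP2 0.0577, CHRM3-AS2 0.135, S100A8 0.0646, PAN2 0.0678, THBS1 0.0738, CDT1 0.102, CD79B 0.0715, PRF1 0.104, ROBO4 0.0624 and CRB2 0.369. Leaving out MOLM-13 DDX6 shRNA replicate 1 gave NRP2 0.112, BAIAP2L2 0.0872, CHRM3-AS2 0.799, S100A8 0.0714, PAN2 0.0804, THBS1 0.268, TYMS 0.144, NDUFB10 0.0706, MT-CYB 0.165, CD79B 0.0946, ZNF121 0.0612, TNFAIP8 0.103, SOCS1 0.0579, HSPA1B 0.0891 and CRB2 0.128. With MOLM-13 DDX6 shRNA replicate 2 left out, values were NRP2 0.0533, S100A8 0.0917, PAN2 0.107, TYMS 0.0778, CDT1 0.28, NDUFS5 0.129, ZFP36L2 0.0708, TNFAIP8 0.102, CD40 0.126, MT-CO1 0.104, PTPN9 0.0633, ROBO4 0.0722 and CRB2 0.134.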

How the results depend on the processing

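No named gene or list called both in the report and under an alternative changed direction. RLE, upper-quartile scaling and fits of each line alone moved the median gene by at most 0.0348 on the log2 scale. The share of rises among HEL calls still went from 59.54% as reported to 53.18% with upper-quartile scaling and 52.04% with HEL fitted alone (59.03% with RLE). RLE and upper-quartile scaling, the stricter filter and the robust prior left every count of calls within 1.5 times the reported one. The labels number the replicates 1 and 2 in every group but do not tie a number to a shared culture or day. Same-numbered libraries deviated from their group means with a correlation of 0.0992 in HEL and -0.1127 in MOLM-13 across 12316 genes, which does not pair them. With the replicate block, 5253 genes were called in HEL, 4927 in MOLM-13 and 2106 for the difference, of which 5247, 4920 and 2105 were reported calls in the same direction, and no list's call within a line changed; the difference calls of p53 targets, immediate early genes, ATF4 targets and glycolysis and hypoxia ended (adjusted p = 0.0541 for each). With MOLM-13 numbers crossed, added after seeing the data, the block gave 6781, 6192 and 3547. There the difference calls of p53 targets and immediate early genes ended (camera adjusted p = 0.0549 and 0.0604). P-body and mRNA decay factors in HEL and mitochondrially encoded mRNAs for the difference passed (camera adjusted p = 0.0473 and 0.0451). Depth limits genes near 3 counts, whose folds are bounds or wide intervals.

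DESeq2 called 3561 genes in HEL (2178 higher, 1383 lower), 1405 lower in MOLM-13, 1494 for the difference (803 and 691), and 1382 in both lines in the same direction (509 lower). All 3561 HEL calls were reported calls in the same direction. Against a fold of 1.2, 2414 genes passed in HEL (1619 and 795), 2557 in MOLM-13 (1649 and 908), 1048 for the difference (610 and 438), and 651 in both lines (460 higher, 191 lower); this test asks for a larger change by construction. At an adjusted p under 0.01, 1541 genes were lower in HEL and 1514 in MOLM-13. Removing the GC trend without centring, added after seeing the data, gave 1156 genes higher and 1506 lower in both lines (1267 and 885 as reported). Of HEL calls 49.34% were higher, against 59.54% as reported, and of MOLM-13 calls 46.14% (2853 higher, 3331 lower) against 55.83%; this form also rescales each library. With no filter camera called 8 lists in MOLM-13. With an estimated correlation camera called 1 list in HEL, 1 in MOLM-13 and 2 for the difference. For cholesterol biosynthesis in HEL the estimate was -0.018, below the preset 0.01, yet camera's unadjusted p went from 6.94e-06 to 0.00756. For megakaryocyte and platelet genes in HEL it was -0.003, and p went from 7.34e-13 to 0.00116. This argues against correlation between members as the cause in these lists. The same holds for other lists with an estimate below 0.01. Among them were stromal, endothelial and epithelial markers in HEL (-0.032, p from 0.00199 to 0.0316) and histones in HEL (0.005, 0.00877 to 0.0528). For the difference they included p53 targets (-0.007, 0.0123 to 0.0447) and immediate early genes (-0.022, 0.0198 to 0.0584). Interferon-stimulated genes in HEL had 0.012, near the preset, and p went from 0.00157 to 0.0369. Ribosomal proteins in HEL had an estimate of 0.705. For the other lists the cause was not tested. Directional fry called p53 targets in HEL higher (adjusted p = 0.0287, list median -0.0256), where camera's direction was down without a call; it called 9 lists in MOLM-13, and mixed fry 23 in HEL, 24 in MOLM-13 and 22 for the difference; neither sets a list against other genes. For DESeq2, the GC trend and the filter the cause was not tested.

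Leaving out each library in turn gave 3713 to 6650 calls in HEL (2250 to 3500 higher, 1463 to 3151 lower), 1454 to 2285 lower genes in MOLM-13, 1489 to 3215 calls for the difference (820 to 1877 more positive, 667 to 1338 more negative), 4 to 9 lists in MOLM-13, and 8 to 13 for the difference. The lowest HEL counts came without HEL control replicate 2 and the lowest count for the difference likewise, at 1489; the highest HEL total came without either MOLM-13 control replicate (6650 each) and the highest counts for the difference without MOLM-13 control replicate 1. The 9 lists came without MOLM-13 control replicate 2. A group left with 1 library and the loss of the widely spread MOLM-13 controls from the pooled spread are part of these fits by construction. Of named gene results, called or not, 465 stayed on their side of the threshold without HEL control replicate 1, 25 lost a call and 2 gained one; without MOLM-13 DDX6 shRNA replicate 1, 460 stayed, 28 lost a call and 4 gained one.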

Other observations

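The gene lists used here were chosen after seeing the data, and the tests of MHC class II genes and of AU-rich coding sequences were chosen only after their result was seen. MHC class II genes, which encode the proteins that present antigen to helper T cells and their regulator CIITA, rose with DDX6 shRNA. Of 13 genes 9 rose and 0 fell in HEL and 12 rose and 0 fell in MOLM-13, with the same counts when adjusted over the list alone. By camera, adjusted over the 4 tests of these lists, the p was 6.19e-06 in HEL and 1.75e-23 in MOLM-13 (adjusted p = 0.0832 and 0.00969 with an estimated correlation). HLA-DRA went from 7.48 to 26.7 CPM in HEL (log2 fold change 1.83 ± 0.12) and from 459 to 1467 CPM in MOLM-13 (1.68 ± 0.06). The invariant chain gene CD74 rose by 0.64 ± 0.07 and 0.86 ± 0.06, HLA-DPA1 by 0.94 ± 0.08 and 1.80 ± 0.07, and CIITA by 0.36 ± 0.14 and 1.03 ± 0.10. In MOLM-13 the exception was HLA-DOB (0.06 ± 0.14, edgeR adjusted p = 0.805), and in HEL HLA-DQA1, HLA-DQB1, HLA-DOA and HLA-DOB, all under 0.5 CPM there, were not called. HLA genes resemble each other and can share reads. Interferon also induces this class, so a shared response with the interferon-stimulated genes may account for part of the rise, and a response to the hairpin stays open as for those genes.

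Translation factor and other mRNAs that begin with a 5' terminal oligopyrimidine tract, the motif that ribosomal protein mRNAs carry, fell on balance in both lines. Of 21 tested genes outside the ribosomal protein list, 15 fell and 2 rose in HEL and 8 fell and 2 rose in MOLM-13, again with the same counts adjusted over the list alone. Camera gave an adjusted p of 1.1e-07 in HEL and 0.000922 in MOLM-13, and neither call held when the correlation was estimated (adjusted p = 0.0832 and 0.193 with an estimated correlation). In HEL the initiation factor gene EIF4B fell by 0.66 ± 0.06 on the log2 scale, the snoRNA host gene GAS5 by 0.50 ± 0.06, PABPC1 by 0.46 ± 0.05 and the elongation factor gene EEF2 by 0.44 ± 0.05. SNHG1 fell by 0.62 ± 0.07 and HNRNPA1 by 0.57 ± 0.05 in MOLM-13. NPM1 rose in both lines (0.15 ± 0.05 in HEL and 0.17 ± 0.05 in MOLM-13), and VIM rose in MOLM-13 by 0.23 ± 0.06. The fall of the ribosomal protein mRNAs may thus extend to other mRNAs of this class, as a hypothesis found and tested on the same data.

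A further hypothesis was that mRNAs with AU-rich coding sequences, known from other work to gather in P-bodies, would rise when DDX6 falls, so that the log2 fold change would fall with the GC content of the last codon positions (Spearman's rho under -0.2). Across genes of at least 5 CPM rho was 0.0915 in HEL (10264 genes) and 0.0806 in MOLM-13 (10218 genes), so the predicted negative correlation was not seen. These fold changes kept any GC trend of the libraries, which could hide or produce such a correlation. The test therefore cannot decide whether these mRNAs rise. Genes are not independent replicates, and total RNA does not show where in the cell an mRNA was.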
